A study of Homo sapiens with 4 samples.

How the data were processed

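Total RNA of 4 MDR variants of TC-71 (1 array each, n = 4) and of the parental line was compared on 2-colour Agilent Human 1 cDNA arrays. Per the labels' protocols, RNA was extracted with Trizol and labelled with a direct-label cDNA synthesis kit, the variant with Cy5 in channel 1 and the parental line with Cy3 in channel 2 on every array. No dye swap is among the arrays, so that a dye effect cannot be told apart from a difference between variant and parental line. The parental line was treated as 1 control sample, and the spread between parental cultures is left out of every test; differences in the parental channel between the arrays enter each ratio and so the errors. The labels do not say whether the parental RNA on the 4 arrays came from separate cultures, so that p-values measure the spread between these 4 arrays only, and their number limits the precision.

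The deposited scanner tables hold, per the file headers, the spot intensity and local background intensity of each channel, the background-subtracted intensity and a normalized intensity in which channel 2 was multiplied by 1 factor per array. The scanner, software and version are not given in the sources used here. The deposited series matrix holds log2 ratios with a median of 0 on each array. Set against the scanner tables, its values were the log2 ratio of channel 1 over channel 2 (Pearson r over spots of 1 for arrays C and D, 0.957 for A and 0.935 for B), and on A and B the authors applied a further step that is not stated. Its scale and direction were thereby found, while that step stays unknown. Columns of other series numbered 0.

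Intensities were corrected with normexp (offset 50) and normalized by loess within each array in R 4.3.3 with limma 3.58.1. Spots that are not probes had weight 0 in the loess and were then left out, and the spots of 1 probe were averaged. The tables lack flags for spots well above background or for outliers, which the planned filter assumed. A probe was therefore called above background when its background-subtracted intensity exceeded a threshold set from the 879 blank spots of that array and channel. The threshold was their median plus 2.6 median absolute deviations, scaled as R does by default to match the SD of normal noise. Between 4.1% and 7.85% of blank spots exceeded it in the variant channel and between 4.32% and 6.94% in the parental channel, and 6 blank spots would have passed the whole filter. Tested probes were above background on all 4 arrays in the same channel, which was the variant channel for 1430 probes, the parental channel for 322 and both for 306. The filter thus favours probes that are bright in the variants: of 154 genes called higher, 14 were above background in the parental channel on all 4 arrays. The SD of a single spot, estimated from the differences between duplicate spots of 108 probes, was 0.50, 0.62, 0.37 and 0.16 (log2) on arrays A to D.

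The arrays give accessions and full names of old design. Of the tested probes, 106 were named by a RefSeq accession in the reference table (assembly GRCh38.p14), 842 by a hand-made match of the deposited full name to a current symbol, and 498 have no symbol and keep their cluster or probe number. The values of ABCB1, ABCB4, LGALS3BP, SRI, LGALS1 and HSP90AA1 had been seen when the match was made. A gene with several tested probes is represented by the brightest. Each gene's log2 ratio was tested against 0 with lmFit and eBayes in limma, and p-values were adjusted by Benjamini-Hochberg at 0.05 over all tested probes. Errors of log2 ratios are limma's standard errors. A gene not above background in the parental channel on any array has only a bound, computed from channel log2 signals after loess and Aquantile and open to dye bias. Of 32 fixed gene lists, 21 had at least 5 tested genes and entered camera (preset correlation 0.01, or estimated) and fry; 11 were too small and are given as counts. Numbers of genes at least 2-fold apart on single arrays and correlations between arrays have no test.

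Named genes were chosen by a fixed rule: ABCB1 and LGALS3BP, the 12 genes of each direction with the largest mean log2 ratio among genes with a symbol that passed with 1 sign on all 4 arrays, up to 4 members of each list with the largest absolute mean, and tested genes of the ABCB1 neighbourhood. A few genes that the rule or the flags selected are not reported here, while the counts include them. The grouping, the tests, the lists, this rule and the first set of alternatives were fixed before the data were examined. These were background correction, normalization, dim-probe filters, variance moderation, array weights, a test against 1.5-fold, probe averaging, saturated spots, the series matrix and leaving out each variant. Centring or loess on the tested probes, a filter in which the channel may differ between arrays, filters by mean intensity or by the parental channel, and variants A and B or C and D alone were added after seeing the data.

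The workflow was tested on simulated arrays made from the mean levels of the real spots with 200 changed genes, and 785 simulated probes passed the filter. Noise was independent between probes, channels and arrays with 1 SD (0.34 per channel, log2). There was no shared parental sample or dye effect, so that the counts need not hold for the real data. Of 50 genes simulated at each size, those that failed the filter are left out of the recovery. The workflow recovered 32 of 32 tested genes lowered by 2 on the log2 scale, 29 of 29 lowered by 1, 35 of 40 raised by 1 and 40 of 40 raised by 2. It called 11 of 644 unchanged probes, 7.48% of its calls. A list of 16 genes raised by 1 gave an adjusted p of 0.0545 in camera, just short of the threshold, and raised by 2 gave 1.21e-10. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Levels of sex-linked marker genes were not reported.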

Results

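Gene expression was compared between 4 multidrug-resistant (MDR) variants of TC-71, an established Ewing sarcoma cell line, and the parental TC-71 line. The labels describe the variants, here called A to D, as overexpressing MDR-1, the drug efflux pump P-glycoprotein encoded by ABCB1, and as having lost the ability to form metastases. The question was which genes accompany this shared phenotype. Each variant was hybridised once, labelled with Cy5, together with Cy3-labelled parental RNA on an Agilent Human 1 cDNA array, so that the comparison rests on 4 arrays. Between 16.6% and 34.6% of probes were above background in the variant channel, and between 6.24% (array B) and 26.5% (array D) in the parental channel. Of 12814 probes, 1446 were tested, which stood for 1264 genes, 789 of them with a gene symbol.

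Among genes with a symbol, those with the largest measured rise in the variants were 3 interferon-induced membrane proteins that restrict virus entry. LGALS3BP, the secreted galectin-binding glycoprotein named in the study's title, also rose, but has only a bound, since the parental channel was not above background, and its rank is uncertain. Ratios are variant over parental, a direction that is likely because the labels place the variant in Cy5 and channel 1, and because the channel 1 over channel 2 ratio of ABCB1 was above 0. IFITM3 rose 6.01-fold (log2 ratio 2.59 ± 0.30, SE, n = 4), IFITM2 5.69-fold (2.51 ± 0.24) and IFITM1 4.93-fold (2.30 ± 0.24), with adjusted p of 0.00331, 0.0031 and 0.0032 in limma. Among the other genes with a symbol and a parental signal above background on at least 1 array, the largest rises were those of EIF3E, a subunit of a translation initiation factor (2.11 ± 0.26), ABCB4 (1.98 ± 0.38), IRS1, the adaptor of insulin and IGF receptors (1.90 ± 0.33), B2M, the light chain of MHC class I (1.77 ± 0.27), and the glutathione transferase GSTM3 (1.66 ± 0.31). TPT1, the ER chaperone CANX and the membrane protein ITM2A rose by 1.65, 1.63 and 1.60 on the log2 scale. The parental channel of ABCB4, IRS1, GSTM3 and ITM2A was above background on only 2 of 4 arrays, so that the size and order of these rises are uncertain. The largest falls among genes with a symbol were those of the LIM-domain protein CRIP2 (−1.54 ± 0.26, adjusted p = 0.0137), the linker histone H1-2 (−1.38 ± 0.25), the respiratory complex I subunit NDUFV1 (−1.25 ± 0.28), the NEDD8-conjugating enzyme UBE2M (−1.21 ± 0.28) and ATF4, the transcription factor of the amino acid response (−1.19 ± 0.27). The chaperonin subunit CCT3, the neuronal enolase ENO2, the fatty acid desaturase FADS2, the glutamine transporter SLC1A5, the mitochondrial chaperone TRAP1, the isocitrate dehydrogenase subunit IDH3B and the serine hydroxymethyltransferase SHMT2 were lower by log2 ratios between −1.17 and −0.95. These 24 genes had the same sign on all 4 arrays. A second tested probe gave a similar ratio for EIF3E (2.03) and CCT3 (−1.19), a smaller one for GSTM3 (0.84, adjusted p = 0.0343), and values that did not pass for IRS1 (0.29) and IDH3B (−0.13).

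**Figure D1:**
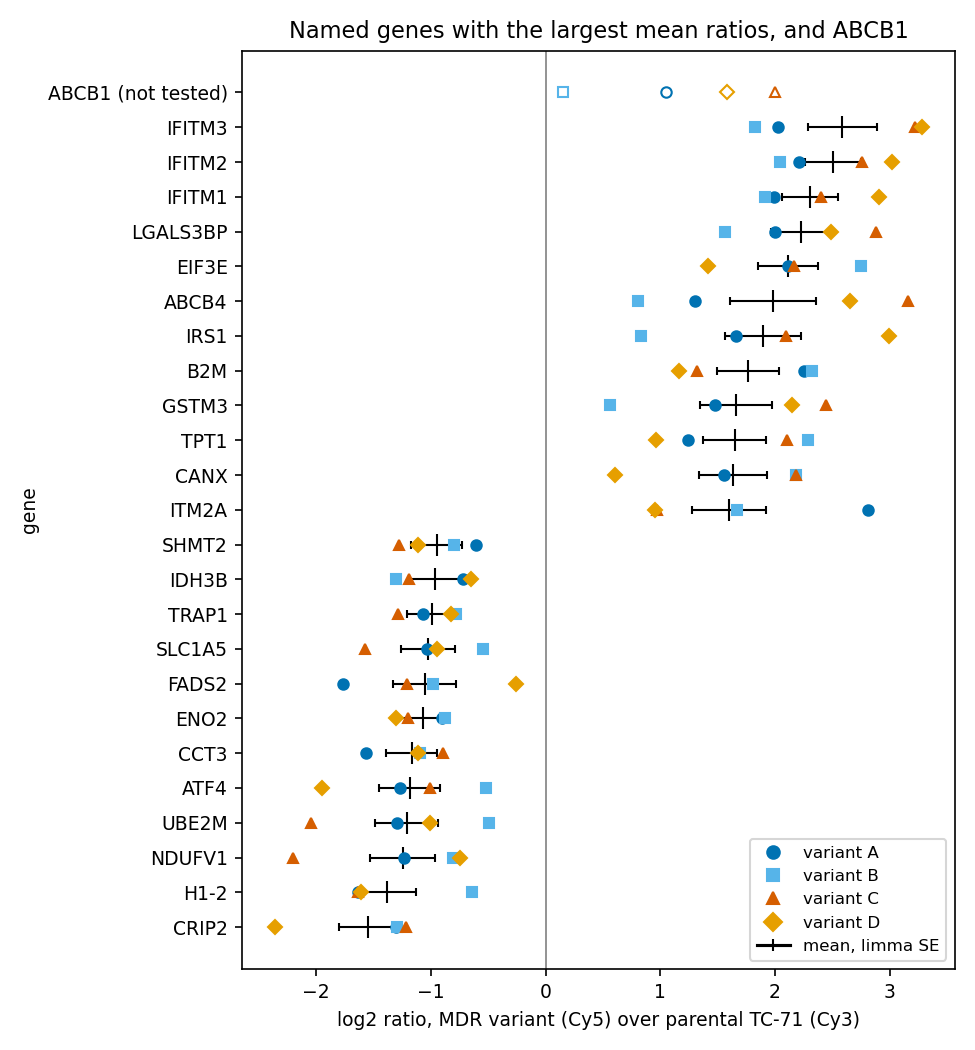
Log2 ratios (horizontal axis) of ABCB1 and of the 12 genes with the largest mean ratio in each direction among genes with a symbol that passed with 1 sign on all 4 arrays (vertical axis), with a symbol for each of the variants A to D and a bar for the mean ± SE from limma; ABCB1 (open symbols) was not tested and has no bar. IFITM1, IFITM2 and IFITM3 lie above 1.5 on all 4 arrays, LGALS3BP has only a bound because the parental channel was not above background, and ABCB1 runs from 0.15 in variant B to 2.001 in variant C.

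In all, 192 of 1264 genes changed at an adjusted p under 0.05, 154 of them higher and 38 lower in the variants, and 467 had an unadjusted p under 0.05. Of the 154 higher genes, 138 were above background in the parental channel on some arrays only, so that the size of their rises is uncertain. The median of the mean log2 ratios of all tested genes was itself 0.34. With each array centred on its tested probes, which lowers the log2 ratios by 0.32 on average, 166 genes changed, 65 higher and 101 lower, and 103 genes were called in both. Centred in this way, the 24 genes kept their direction and their side of the threshold, with log2 ratios of 2.27 for IFITM3, 1.66 for ABCB4, −1.86 for CRIP2 and −1.50 for ATF4. Of the 48 named genes that passed, 8 did not pass after centring, among them HLA-C, ITGB1, KIF20A, SCD, ALDH1A1, MACROH2A1 and ATP5F1A. The split was 268 higher and 11 lower with median centring in place of loess, and 0 genes were lower with the scanner software's ratios (154 higher) or the deposited series matrix (187 higher). Of the 12 largest named falls 3 passed with median centring and 0 with either of the other 2 scalings (log2 ratios of −0.87 to −0.30 with the scanner software), while of the 12 rises all passed with median centring and all but ABCB4 with the other 2. Every fall given for a list below is therefore lost with the scanner software and the series matrix. The split was 66 higher and 94 lower with loess fitted on the tested probes. Among probes above background in both channels, 53 genes changed, 16 higher and 37 lower. Without variant A 21 genes changed, without variant B 107 and without variant D 3, which were IFITM1, IFITM2 and EIF3E. Variants A and B alone gave 476 calls and C and D alone 93.

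**Figure D2:**
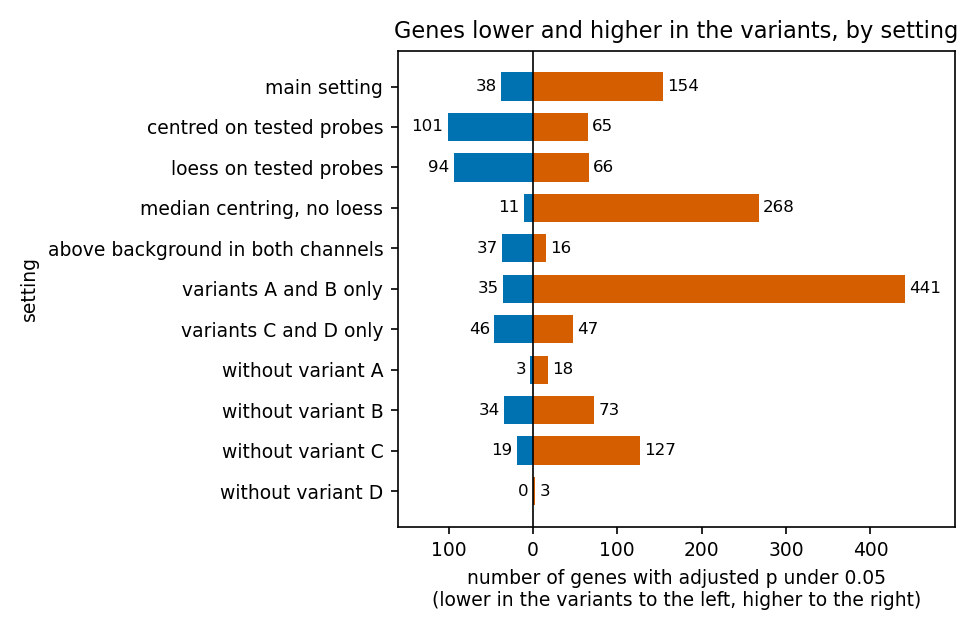
Number of genes with an adjusted p under 0.05 (horizontal axis), lower in the variants to the left of 0 and higher to the right, for each setting or choice of arrays (vertical axis). The bars show 154 higher and 38 lower genes in the main setting, 65 and 101 after centring on the tested probes, and 3 and 0 without variant D.

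ABCB1 itself was measured close to background. Its brighter probe gave log2 ratios of 1.05, 0.15, 2.001 and 1.58 in variants A, B, C and D. It was above background in the variant channel on 3 of 4 arrays and in the parental channel on 0, so that it was not tested and its fold change is uncertain. Because its ratio helped to set the direction, its sign is not a separate finding. A second ABCB1 probe was at background, with a mean log2 ratio of 0.03. ABCB4, the neighbouring gene for a phospholipid transporter of high sequence similarity, rose by 1.98 ± 0.38 (adjusted p = 0.0206, higher on 4 of 4 arrays). Because ABCB1 transcripts can bind a probe of so similar a gene, this value is uncertain. The call of ABCB4 held in 14 of 20 alternative settings. Of the 50 listed genes around ABCB1 in 7q21, 25 had a probe and 3 were tested, of which ABCB4 rose and SRI (0.22 ± 0.23) and STEAP1 (0.22 ± 0.31) did not pass. Of 38 listed ABC transporters 25 had a probe, and the other tested one, the cholesterol exporter ABCA1, had a log2 ratio of 0.21 ± 0.22. LGALS3BP was above background in all 4 variants and in the parental channel on 0 of 4 arrays. It was at least 2.99-fold higher in the variants (measured log2 ratio 2.23 ± 0.26, adjusted p = 0.00331), with log2 ratios of 1.998, 1.56, 2.88 and 2.49 in A to D. Of the 5 tested genes of the galectin list it alone passed, or 2 higher and 1 lower adjusted over the list alone and 1 higher and 1 lower after centring. LGALS8 (0.73, adjusted p = 0.062) and LGALS1 (0.57, adjusted p = 0.229) did not.

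Of 10 tested interferon-response genes, 4 rose, namely IFITM1, IFITM2, IFITM3 and LGALS3BP, and 0 fell; 5 rose adjusted over the list alone, and 4 with arrays centred on the tested probes. IRF9, a subunit of the interferon-activated transcription factor, had a log2 ratio of 0.50 and WARS1, the interferon-inducible tryptophanyl-tRNA synthetase, −0.32, neither of which passed. Among 12 genes of MHC class I antigen presentation, those that rose included B2M, the heavy chain HLA-C (1.31 ± 0.33, adjusted p = 0.0344) and CANX, and the ER chaperone CALR fell (−0.71 ± 0.21, adjusted p = 0.0499). Adjusted over the list alone 6 rose and 1 fell, and with centred arrays 3 rose and 1 fell over all genes. HLA genes and the 3 IFITM genes are near-identical within each family, so that their separate values are uncertain. The tested MHC class II gene HLA-DMB (0.29) did not pass.

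Detoxification genes included 3 of 16 that rose and 0 that fell, GSTM3, its relative GSTM2 (1.14 ± 0.22) and the aldehyde dehydrogenase ALDH1A1 (0.83 ± 0.22); adjusted over the list alone 4 rose, and with centred arrays 2 rose and 1 fell. The parental channel of ALDH1A1 was above background on only 1 of 4 arrays and that of GSTM2 on 2, so that the size of these rises is uncertain. MGST1 (0.91, adjusted p = 0.0758) did not pass. In the IGF axis, on which Ewing sarcoma cells depend for growth, IRS1 rose among 4 tested genes, while IRS2 (0.63, adjusted p = 0.204) did not pass. Of 15 tested genes that EWS-FLI1, the fusion oncoprotein of this tumour, is known to activate, 3 rose, both in the main setting and after centring. They were KDSR (1.47 ± 0.29), the transcription factor MYC (1.36 ± 0.27, with 1.45 and 1.43 from its other probes) and the ubiquitin-conjugating enzyme UBE2C (1.03 ± 0.23), whose second probe did not pass (0.77, adjusted p = 0.0573). Of 7 genes that EWS-FLI1 is known to repress, CCN2 (1.25 ± 0.31) and ITGB1 (0.79 ± 0.21, 0.59 and not passing with its second probe) rose and ACTA2 (−0.94 ± 0.22) fell, against 1 higher and 1 lower after centring. The tested immediate early genes, MYC and CCN2, both rose. Among 5 Ewing and neural markers ENO2 fell (−1.07 ± 0.21), and CD99, the surface marker of this tumour, had a log2 ratio of 0.40 ± 0.21 (adjusted p = 0.188), but passed with median centring (0.84, adjusted p = 0.0351) and the scanner software (0.82, adjusted p = 0.041), in each of which 2 of these markers rose and 0 fell.

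Growth-related lists held several genes that rose, to be set against 154 of all 1264 tested genes. The shares of ribosomal (7 of 47) and oxidative phosphorylation genes (6 of 47) were near the share over all genes. No list passed limma's camera test as a set (adjusted p = 0.957 for ribosomal, 0.83 for oxidative phosphorylation and 0.56 for cell cycle genes). Of 25 cell cycle genes 8 rose and 0 fell, among them the spindle checkpoint gene BUB3 (1.21 ± 0.26), UBE2C and the mitotic kinesin KIF20A (1.02 ± 0.24); adjusted over the list alone 11 rose and 2 fell, and centred on the tested probes 2 rose and 2 fell. Of 47 ribosomal protein genes 7 rose, among them RPS15A (1.21 ± 0.24) and RPS29 (1.19 ± 0.24), and 0 fell, against 6 and 1 after centring. Of 47 oxidative phosphorylation genes 6 rose, such as COX7B (1.28 ± 0.30, 0.42 and not passing with its second probe) and ATP5F1A (1.02 ± 0.25), and NDUFV1 fell; adjusted over the list alone 9 rose and 2 fell, after centring 3 rose and 4 fell, and with median centring 14 rose and 0 fell. NDUFB7 (−1.09, adjusted p = 0.0689) did not pass. In lipid synthesis the desaturase SCD (0.88 ± 0.21) rose and FADS2 fell (−1.06 ± 0.27); adjusted over the list alone 3 rose and 1 fell, and after centring only FADS2 passed. Of 15 genes of the ER stress response, the chaperones CANX and HSP90B1 (1.05 ± 0.25) rose and ATF4, the asparagine synthetase ASNS (−0.79 ± 0.22, adjusted p = 0.0436) and CALR fell, with the same counts after centring on the tested probes but 3 higher and 0 lower with median centring in place of loess. SLC3A2 (−0.79 ± 0.23), a subunit of amino acid transporters, and PCK2 (−0.76 ± 0.22), a mitochondrial enzyme of phosphoenolpyruvate synthesis, also fell. CALR, ASNS, SLC3A2 and PCK2 were named after their values had been seen. Of 18 chaperone genes CCT3 fell and 0 rose, and of 22 proteasome genes 0 passed, with the largest log2 ratios at 0.70 for PSMB2 and PSMA5; after centring on the tested probes 3 and 2 fell, while with median centring 3 chaperone genes rose and 1 fell and 2 proteasome genes rose, and with the scanner software 3 chaperone genes rose and 0 fell. Among 5 histone genes H1-2 fell and MACROH2A1 (0.87 ± 0.22) rose. Of 16 genes of glycolysis and hypoxia ENO2 fell, and PGAM1 (1.03, adjusted p = 0.181) did not pass.

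Lists tied to spread and differentiation were small and held few calls, so that their shares are imprecise. Of 10 adhesion genes, the protocadherin PCDHGC3 (1.25 ± 0.28) and the integrin ITGB1 rose, against 3 higher and 0 lower adjusted over the list alone and 1 higher and 1 lower after centring. Of 7 metastasis suppressors, 6 proteases and inhibitors and 5 matrix genes 0 passed, with the largest log2 ratios of the first 2 lists at 0.54 for the nucleoside diphosphate kinase NME2 (adjusted p = 0.0978) and 0.72 for the protease inhibitor SERPINE2 (adjusted p = 0.0825). NME2 passed with median centring (0.97, adjusted p = 0.0351), the scanner software (0.96, adjusted p = 0.0312) and the series matrix. Of 8 mesenchymal genes of the TGF-beta and WNT pathways ACTA2 fell, and adjusted over the list alone 1 rose and 1 fell. Of 4 apoptosis regulators 0 passed, the largest being BNIP3L (0.65, adjusted p = 0.0612), or 1 higher adjusted over the list alone, and the p53 targets CCNG1 (0.71) and EI24 (0.67) did not pass over all genes. Both p53 targets passed adjusted over their list alone and with median centring, and a second, dimmer EI24 probe passed (1.13, adjusted p = 0.0256). Among 6 tested markers of cell types that this culture should lack, the endothelial ENG, also found on mesenchymal cells, rose (1.21 ± 0.28), and MS4A1 (0.83), CD2 (0.30), KRT20 (0.34), MYL1 (−0.62) and MYOG (0.37) did not pass.

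As sets, 0 of the 21 lists with at least 5 tested genes passed limma's camera test after Benjamini-Hochberg adjustment, and 2 had an unadjusted p under 0.05. The interferon list had a mean log2 ratio 0.81 above the other genes (adjusted p = 0.238), and the ER stress list lay 0.28 below them (mean difference −0.28, adjusted p = 0.445). With an estimated correlation between genes 0 lists passed and 0 had an unadjusted p under 0.05 (interferon p = 0.0839, ER stress p = 0.484). The fry test, which asks whether a list's genes move on balance in 1 direction without setting them against other genes, passed 2 lists, interferon and MHC class I (both adjusted p = 0.0122), and its mixed version 21. The tested genes as a whole lay above 0 (median of the mean log2 ratios 0.34), and fry gave every list an upward direction. The fry results therefore include this general shift, and fry was not run on centred arrays. Without variant B the interferon list passed camera (adjusted p = 0.00773). The ribosomal list passed among probes above background in both channels (adjusted p = 0.00595). Of a few lists the mean, the median and the test differed in sign relative to the other genes, namely chaperones, histones, glycolysis, Ewing markers, ribosomal proteins, adhesion, proteases and EWS-FLI1-activated genes.

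Single variants differed in how many genes lay at least 2-fold from the parental line. IFITM1, IFITM2, IFITM3, B2M and EIF3E were at least 2-fold higher in every variant, as were YWHAE, a phosphoserine-binding adaptor, and SNX7, a sorting nexin, while CRIP2 was at least 2-fold lower in every variant. In all, 13 genes were at least 2-fold higher and 3 lower on all 4 arrays, or 5 and 14 relative to each array's median. On single arrays 283 genes were higher and 42 lower in variant A, 289 and 34 in B, 124 and 136 in C, and 56 and 44 in D. The median log2 ratio of the tested genes was 0.53, 0.60, 0.08 and 0.08 on these arrays. Relative to that median, 129 genes were lower in A, 108 in B, 157 in C and 54 in D, in each variant more than were higher. Array quality differed too. The SD of a single spot (log2) was 0.503 and 0.619 on A and B, against 0.369 and 0.157 on C and D. The parental channel was above background for 10.996% and 6.24% of probes on A and B, against 22.04% and 26.5% on C and D. The larger counts of higher genes on A and B go with these differences, while the counts of lower genes do not. Whether array quality or the variants set the counts was not tested. ITM2A was highest in variant A (2.81), IRS1 in D (2.996) and ABCB4 in C (3.16), but with 1 array per variant such differences have no replicate check. Without variant B 30 genes, and without variant D 39, were at least 2-fold apart in 1 direction on the remaining arrays, against 16 on all 4.

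The log2 ratios of the variants were correlated across the tested genes, which are not independent replicates, with a mean Pearson r of 0.45 over the 6 pairs of arrays. The pairs A and B (r = 0.59) and C and D (r = 0.62) were above the other pairs, which ranged from 0.30 to 0.47. IFITM3 and ABCB4 were higher in C and D, at 3.22 and 3.28 and at 3.16 and 2.66, than in A and B, at 2.02 and 1.82 and at 1.30 and 0.81. B2M was lower in C and D (1.32 and 1.16) than in A and B (2.25 and 2.33), but relative to the median of each array much of this gap is lost (1.72 and 1.72 in A and B, 1.25 and 1.08 in C and D). The arrays share the parental line and the dye orientation. Simulated unchanged variants against 1 shared parental sample, which deviated as much as each variant, gave a mean r of 0.50 and a covariance of 0.29, against an observed covariance of 0.24. The observed values were not above the simulated ones. However, giving the parental sample the same spread as each variant sets the simulated r near 0.50 whatever the data. The comparison therefore cannot tell changes shared by the variants from the effect of the shared parental line. The parental channel, labelled as the same line, correlated at 0.96 between arrays C and D, 0.82 between A and B and 0.75 to 0.84 in the other pairs. The variant channel correlated at 0.92 between C and D, 0.90 between A and B and 0.82 to 0.86 in the other pairs. Both pairs thus stood out in the variant channel, and only C and D in the parental channel.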

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

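The test on the parental channel given here was chosen after its result was seen. Of 113 quantities checked over the 4 variants, 8 had 1 variant far from the other 3, where chance gives about 1 in 20. All but 1 of the 8 are given here. CRIP2 fell furthest in variant D (log2 ratio −2.36, against −1.30, −1.30 and −1.21 in A to C). H1-2 fell least in variant B (−0.65, against −1.64, −1.63 and −1.61). SRI was at 0.73 in variant B and between −0.000364 and 0.08 in the others. The transcription factor CEBPB stood at −3.28 in variant B, against −0.51, −0.36 and −0.25. PAPPA, a protease of the IGF axis, was at −0.30 in variant C and between 0.90 and 1.096 in the others. The kinase MAP2K6 was at −0.61 in variant B and between 0.78 and 1.05 in the others. Variant C had 136 genes at least 2-fold lower, against 42, 34 and 44. Relative to each array's median, variant C stood less apart, with 157 such genes against 129, 108 and 54 in A, B and D.

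Log2 ratios of variants A and B resembled each other, as did those of C and D. A candidate explanation is that the measured parental channel differed between the arrays, although it is labelled as the same line. In the 100 genes whose ratio differed most between the pairs, the parental channel differed opposite to the ratio and by more than the variant channel in 59% (95% exact interval 48.7% to 68.7%). The 100 genes were picked on this same difference and are not independent, so that the interval does not measure the spread between variants. Across tested genes, the difference in ratio correlated at −0.60 with that of the parental channel and at 0.28 with that of the variant channel. Since the ratio is made of these channels, the signs of both correlations are built in. The labels give no batch, but the arrays differed technically in the same pairs. The median intensity of blank spots in the parental channel was 779.9 and 722.3 on A and B, against 579.5 and 588.9 on C and D. The scanner's factor for that channel was 0.806 and 0.704, against 1.097 and 1.07. The authors' further step on the deposited ratios was found on A and B only. The parental channel and real differences between the variants cannot be told apart here, since each variant has 1 array.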

How the results depend on the processing

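The count of 192 changed genes fell to 0 with no filter on dim probes (limma, over 10683 genes, 1049 of them at an unadjusted p under 0.05), 53 above background in both channels and 6 in a test against 1.5-fold. Chosen after seeing the data, other settings gave 13 with probes chosen by mean intensity, 65 with the parental channel above background, 93 for variants C and D only and 476 for A and B only. Leaving out 1 variant gave 3 to 146 calls (3 without D, 21 without A, 107 without B), with fewer arrays in each test; why these variants matter most was not tested. In all other settings the count was within 1.5 times, from 128 without background correction to 279 with median centring (268 higher, 11 lower); a filter in which the channel may differ between arrays gave 146. Lists past camera went from 0 to 9 with no filter, 1 (ribosomal) above background in both channels or in the parental channel, 1 (interferon) for C and D only and 0 to 1 when leaving out a variant, against 2 with directional and 21 with mixed fry. Genes at least 2-fold apart on all arrays went from 16 to 2 above background in both channels and 17 to 39 when leaving out a variant. The mean correlation stayed between 0.39 and 0.51. The split of 154 higher and 38 lower genes turned to more lower than higher genes when arrays were centred on the tested probes (65 and 101), with loess fitted on the tested probes (66 and 94) and above background in both channels (16 and 37); the cause was not settled. No named gene or list changed sign on the significant side of the threshold; values that did not pass and changed sign counted as the same, at most 7 of 106 named genes per setting. Of the 48 named genes that passed, 3 passed without variant D, 13 without A, 35 without B, 35 without C, 24 with C and D only and 40 after centring on the tested probes; IFITM1, IFITM2 and EIF3E passed in 19 of 20 alternatives each. No paired analysis was possible because all 4 variants form a single group of ratios, each of which already sets a variant against the parental RNA on the same array. The scanner's p per spot and a slide or scan block were not run, since the tables used here hold neither. Signal over background limits the parental channel most, with 6.24% of probes above it on array B.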

Other observations

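The tests in this part were chosen after the data had been seen, except the count of sign orientations and the filter on both channels. Several genes outside the fixed lists rose in the variants. Among them were CALM2 (log2 ratio 1.37 ± 0.33), which encodes calmodulin, and YWHAZ (1.23 ± 0.25) and YWHAE (1.31 ± 0.23), which encode 14-3-3 proteins. The aminoacyl-tRNA synthetases TARS1 (1.01 ± 0.22) and NARS1 (0.96 ± 0.27) also rose, as did the cohesin subunit RAD21 (1.52 ± 0.25), the heparan sulfate polymerase EXT1 (1.12 ± 0.25), the interleukin receptor IL15RA (1.18 ± 0.25) and the acute-phase protein SAA1 (1.17 ± 0.28). The Notch ligand JAG2 fell by 0.75 on the log2 scale. These genes, RAD21 and JAG2 included, were named after their values were seen.

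More genes were higher than lower in the variants, 154 against 38. Centred on the tested probes, the share of calls that were higher was 39.2% (95% exact interval 31.7% to 47.02%), which is what loess on all probes, most of them near background, would need if it left expressed genes off 0. Centring evens such a split by itself, however, and genes above background in both channels had a median log2 ratio of −0.06, so that this explanation stays open. The test first used the share alone, by which the explanation would have passed; the condition on genes above background in both channels was added when both values were known. The dim-probe filter, which passes most probes through the variant channel, stays open too: above background in both channels 16 genes were higher and 37 lower, while with probes chosen by mean intensity 84.6% of calls were higher, on 11 of 13 calls (54.6% to 98.1%). A general rise of transcripts in the variants cannot be excluded either, since every normalization here assumes a centre.

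IFITM1, IFITM2, IFITM3, HLA-C and B2M rose together. Binding of near-identical family members to the same probes is argued against for B2M alone. It has no such relative, and its lowest log2 ratio over the 4 variants was 1.16. B2M was counted in this pattern because it rose, so that its passing was fixed in advance and says nothing about the families. Sharing within the IFITM or HLA family stays open. A hypothesis is an interferon-type response of many genes. Of the 7 tested interferon list genes outside the IFITM family, 14.3% (1 gene, LGALS3BP; 95% exact interval 0.361% to 57.9%) passed and were higher, and their mean log2 ratio lay 0.23 above that of the other genes. That excess came from LGALS3BP, which has only a bound; without it the mean of the 6 others lay 0.06 below that of the other genes (difference −0.06). These genes are too few to decide.

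ATF4, ASNS, PCK2, SHMT2, SLC3A2 and SLC1A5, put together after their values were seen, fell in the main setting. None of them passed with the scanner software or the series matrix, where 0 genes were lower, and ATF4 stood at −0.55 (adjusted p = 0.258) with the scanner software, so that the pattern itself depends on the scaling. A hypothesis is a lower ATF4-driven response, which would lower further ATF4 targets too. The 13 tested targets of a further list had a mean log2 ratio 0.21 below the other genes (difference −0.21, camera p = 0.137, or p = 0.479 with an estimated correlation), much of which came from CEBPB, low mainly in variant B (without it, 12 targets, difference −0.11), with 0 called lower and TARS1 and NARS1 called higher, so that the hypothesis was neither borne out nor excluded.

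EIF3E, RAD21, MYC and EXT1 all lie on chromosome 8, which is often gained in Ewing sarcoma. A hypothesis is a higher level of the whole chromosome in the variants. All 28 tested genes of the chromosome, these 4 included, lay on average 0.24 above the genes of other chromosomes, with 8 higher and 0 lower. In camera the adjusted p over all chromosomes was 0.218, or 0.968 with an estimated correlation (unadjusted p = 0.0664 and 0.131). Without the 4 genes that suggested the test, the 24 other genes lay 0.0789 (log2) above the genes of other chromosomes (camera p = 0.43, or p = 0.447 with an estimated correlation); 4 of them rose (YWHAZ, RPL7, COX6C and TCEA1) and 0 fell, so that this test did not decide. Over all 23 chromosomes tested, genes of chromosome 19 lay below the other genes in camera (mean difference −0.32, adjusted p = 0.00795). Those of chromosome 5 lay above the other genes (0.28, adjusted p = 0.025 in camera). Both calls were lost with an estimated correlation in camera (adjusted p = 0.968 for each). Against the parental line, genes of chromosome 19 had a mean log2 ratio of 0.02, with 4 called higher and 3 lower, so that they did not fall as a whole.

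Turning the sign of some arrays shows how far the calls rest on agreement between the arrays. Since all 4 ratios share the parental line and the dye orientation, agreement is expected even without a change in the variants, and this count cannot show a change. The real orientation gave 192 calls, 1 of the 8 orientations gave as many, and the highest of the others gave 0; 8 orientations are too few for a share under 0.05.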
